A study of Danio rerio with 20 samples.

How the data were processed

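RNA was sequenced from 20 libraries of zebrafish embryos in 4 groups of 5 libraries: unexposed wild type, exposed wild type, unexposed tp53 mutant and exposed tp53 mutant. Exposed embryos received 1-naphthol, an aromatic alcohol, at 20 µg per 5 mL from 24 to 72 hours post fertilization (hpf). Wild-type embryos formed experiment 1 and mutant embryos experiment 2, so genotype and experiment divide the libraries in the same way. The sample labels call the allele mutant or knock out and do not name it. Although the series title refers to Gata1+ erythroid cells, the labels give embryos as the RNA source and mention no sort. How many embryos went into each library is not given in the sources used here, and p-values measure the spread between these samples, which may be technical.

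The deposited values were raw read counts per gene, which the authors left unnormalised, for 14456 genes named by symbol. Per the submitters' processing notes the tools were FastQC, Trimmomatic, TopHat2 2.0.13, Subread, featureCounts and limma, with genome build danRer7. The gene annotation, the strand setting, the treatment of reads that map to several genes and the method of library selection are not given in the sources used here. Values of genes with close relatives, such as globins, crystallins, opsins, keratins and heat shock genes, therefore carry an unknown share of reads that another member could claim. Chromosome positions and exon numbers were taken from the count table on danRer7. A later zebrafish gene table served only to match older symbols through synonyms, not for positions.

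Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 11334 genes and removed 3122. Library sizes were scaled by the trimmed mean of M values (TMM). A robust quasi-likelihood fit with 1 mean per group and 16 residual degrees of freedom gave a log2 fold change and a two-sided p for each gene, adjusted by Benjamini-Hochberg. A gene was called at a false discovery rate (adjusted p) of 0.05, with no fold threshold. The standard error (SE) of a fold change was taken as its size divided by the square root of F. Levels are CPM, read counts scaled to a common library size by TMM, as mean ± SD over libraries, and log2 CPM used a prior count of 2. Where a group had 0 reads of a gene, its fold was bounded by a floor of 3 counts over the group, and with 1 to 3 reads the ratio was given with its exact 95% counting interval. Both cover counting error only.

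The comparisons were exposure in wild type, exposure in mutants, the difference of those effects, and unexposed mutants against unexposed wild type. The overlap of the exposure effects was tested by a one-sided Fisher exact test among the tested genes.

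Genes were also tested in 35 fixed lists. They covered p53 targets, Nrf2 and glutathione response, antioxidant enzymes, Ahr targets, conjugation enzymes, erythroid markers, heme synthesis, heat shock response, unfolded protein and integrated stress response, glycolysis, hypoxia response, DNA replication and cell cycle, apoptosis and inflammation and acute phase. Others were circadian clock, sterol synthesis, ribosome proteins, oxidative phosphorylation and the mitochondrial genome. The tissue and cell lists were neurons, photoreceptors, lens, skeletal muscle, heart muscle, liver, exocrine pancreas, intestine, neutrophils and macrophages, endothelium, cartilage and bone, epidermis, ionocytes, pigment cells, hatching gland, and glia and progenitors. The mitochondrial genome list had 0 members in the table, which left 34 lists. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 34 lists of a comparison, and again with the correlation estimated from the data. The limma test fry asked whether members moved one way on balance, or in either direction. A list score, the mean log2 CPM of the tested members in a library, was compared between groups by a two-sided exact permutation test over 252 splits, whose smallest possible p is 0.00794. For the difference of the exposure effects, the exposure assignments were permuted within genotype. Member counts are given over all tested genes and adjusted over the list alone.

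Named genes followed a rule. For each comparison it took up to 10 higher and 10 lower called genes with the largest fold changes. These needed a mean of at least 1 CPM in a group, a symbol that is not a clone or locus placeholder, and no overlap between the libraries of the groups. From each list it took up to 4 called members with the smallest adjusted p, or up to 2 members as values only where none was called. The genes tp53 and gata1a were always named, and for the difference up to 10 genes with the smallest adjusted p. The text gives part of this set in full and summarises the rest, and where few genes were called under another setting they are named although their values had been seen.

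Depth ranged from 1176919 to 13304175 counts per library. The fit was tested on simulated data of the same size, with 200 of 11334 genes changed. It recovered between 14% and 19% of 2-fold changes and between 64% and 77% of 4-fold changes, and between 1.19% and 3.23% of its calls were false. The simulated libraries differed only in depth, the added changes and independent noise, without the division between real libraries described in the Results. The false share therefore need not hold for the real data. Of 200 simulated unchanged lists of 30 genes, camera gave an unadjusted p under 0.05 to 0.5%. Because the simulated noise was independent, the members of these lists were not correlated. That share therefore cannot show how often camera calls unchanged lists in the real data, where members may be correlated. All 40 pairs of libraries within groups differed by more than counting noise, the closest with a chi-square per degree of freedom of 7.87, so no library was a copy of another in its group.

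The groups, the tests, the lists, the naming rule and a first set of alternatives were fixed before the data were examined. That set comprised other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, 1 surrogate variable from sva 3.50.0, a fold threshold of 1.5, each genotype or exposure alone, replicate blocks, and leaving out each library in turn. After the data were seen, fits were added with a term for the libraries whose sample descriptions carry the number 4 or 5, with these or the other libraries alone, and with the description number as a block. The numbers in the descriptions differ from those in the sample titles in the exposed groups. Numbers 6 and 7 occur only in exposed groups and number 2 only in unexposed groups. Any effect of these numbers cannot be told apart from exposure. Shared numbers were checked by correlating libraries after removing group means. By description number, the 4 mutant pairs gave r between 0.251 and 0.355 and the 5 pairs of unexposed libraries across genotypes between 0.272 and 0.653, and with every r over 0.1 these were taken as paired. Only 2 of the 4 and 2 of the 5 unexposed mutant libraries correlated best with the library of their own number, so the shared division of the numbers 4 and 5 could account for these r. The 3 wild-type pairs gave between 0.0402 and 0.491 and were not taken as paired. No library was left out of the fits that the results rest on.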

Results

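Gene expression was measured by RNA sequencing in zebrafish embryos, with 5 libraries in each of 4 groups: wild type and tp53 mutant, each unexposed or exposed to 1-naphthol from 24 to 72 hpf. Total counts ranged from 6308455 to 10600037 in unexposed wild type, from 1176919 to 12853855 in exposed wild type, from 6109535 to 8424798 in unexposed mutants and from 2974594 to 13304175 in exposed mutants. Between 12441 and 13435 genes had at least 1 count in a library. The keratin gene krt4, made in the surface layer of the embryonic skin, took 6.69% ± 2.97 (SD, n = 5) of counts in unexposed wild type and 6.48% ± 4.75 in exposed wild type. It took 10.5% ± 3.8 in unexposed mutants and 11% ± 3.07 in exposed mutants. The first principal component held 34.1% of the variance and followed the numbers in the sample descriptions. Being numbered 4 or 5, as 2 libraries of each group are, accounted for 0.67 of its variance, against 0.00879 for exposure and 0.213 for genotype. The second held 16.1%, with 0.514 of its variance accounted for by exposure.

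**Figure D1:**
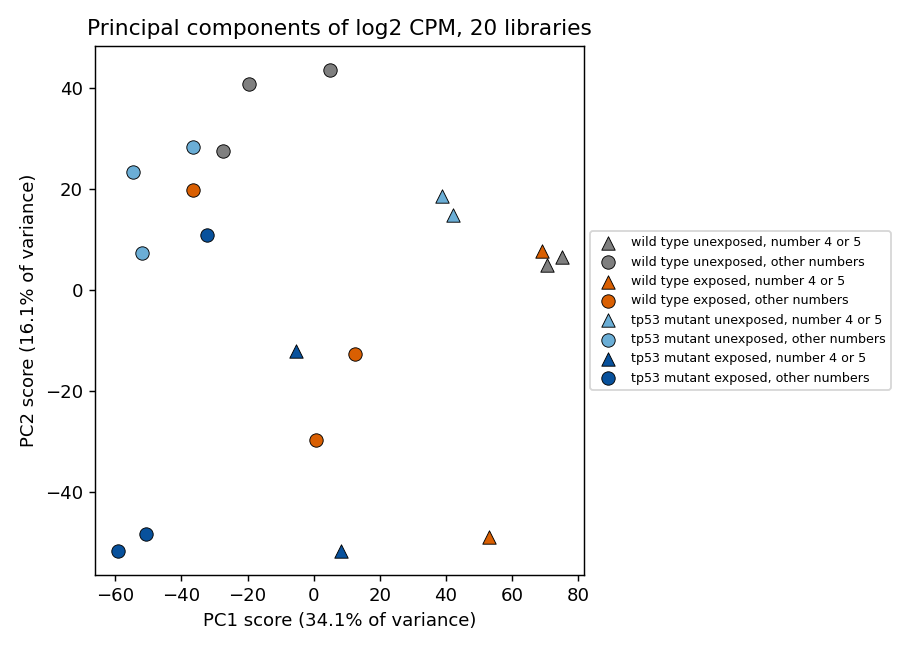
Principal components of log2 CPM for the 20 libraries, with component 1 (34.1% of the variance) on the horizontal axis and component 2 (16.1%) on the vertical axis, in units of the component scores. Colour gives the group and triangles mark the libraries numbered 4 or 5 in the sample descriptions, whose mean on component 1 was 43.9 against -29.3 for the others.

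The tp53 gene itself (chromosome 5, 25755162 to 25766734, 11 exons on danRer7) was expressed in every library. In unexposed wild type, tp53 stood at 84.7, 103, 97.5, 53.3 and 69.4 CPM (mean 81.5 ± 20.4, SD, n = 5), and in exposed wild type at 50.8, 56.4, 66.6, 93.2 and 54.8 CPM (64.3 ± 17.2). In unexposed mutants it stood at 63.9, 55.5, 67.8, 50.7 and 51.9 CPM (57.9 ± 7.55), and in exposed mutants at 40.3, 53.1, 43.8, 53.4 and 46.4 CPM (47.4 ± 5.76). The log2 difference of unexposed mutants from unexposed wild type was -0.49 (SE 0.197, adjusted p = 0.251). The exposure effect was -0.34 in wild type (SE 0.198, adjusted p = 0.534) and -0.29 in mutants (SE 0.198, adjusted p = 0.533). A mutant allele can leave RNA levels in place, so these values do not test the genotype. The erythroid transcription factor gene gata1a (chromosome 11, 26345473 to 26352417, 6 exons) was scarce. It stood at 2.27 ± 1.52 CPM in unexposed wild type, 2.78 ± 1.44 in exposed wild type, 3.87 ± 3.19 in unexposed mutants and 1.53 ± 0.744 in exposed mutants. Its log2 exposure effect was 0.38 in wild type (adjusted p = 0.887) and -1.28 in mutants (SE 0.673, adjusted p = 0.386).

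The first comparison asked how wild-type embryos respond to 1-naphthol, and 4 genes were higher in exposed embryos. The largest fold change was that of cyp1a (chromosome 18, 4974676 to 4985563, 7 exons), a cytochrome P450 gene induced through the aryl hydrocarbon receptor, Ahr. It went from 0.37 ± 0.208 CPM to 7.51 ± 2.97 CPM (SD, n = 5 per group). This was a 20.1-fold rise (log2 4.33, SE 0.691, adjusted p = 0.0137). The tyrosine breakdown gene hpdb (chromosome 8, 35868758 to 35879011, 14 exons) rose 6.65-fold, from 2.15 ± 0.817 to 14.8 ± 4.95 CPM (log2 2.73, SE 0.382, adjusted p = 0.00614). The gene phyhipla (chromosome 17, 20793645 to 20809230, 5 exons) rose 5.51-fold from 1.75 ± 0.599 to 10.1 ± 6.15 CPM (log2 2.46, SE 0.422, adjusted p = 0.0266). The neural RNA-binding protein gene celf4 (chromosome 21, 10503904 to 10690751, 13 exons) rose 4.32-fold from 40.0 ± 9.24 to 173 ± 105 CPM (log2 2.11, SE 0.335, adjusted p = 0.0137). For all 4, the lowest exposed library stood above the highest unexposed library. In this comparison edgeR called 4 genes higher and 0 lower, and 1293 genes had an unadjusted p under 0.05. DESeq2 called 110 higher and 62 lower, and limma-voom called 0. The count was 0 without unexposed library 2, 1 without unexposed library 3, 4 or 5 (hpdb each time) and 20 without exposed library 2, and each of the 4 genes lost its call in at least 1 of these fits. The 10 wild-type libraries alone gave 2, cyp1a and hpdb. The count was 99 (65 higher, 34 lower, all 4 genes included) with a term for the libraries numbered 4 or 5, 0 among those libraries alone and 578 among the others. The others compare exposed libraries numbered 3, 6 and 7 with unexposed ones numbered 1, 2 and 3, so the numbers are partly confounded with exposure there. Of 100 splits of the 10 wild-type libraries, 6, the real one included, gave at least 4 genes.

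Among the wild-type lists, camera found 8 shifted, none of them with an estimated correlation (adjusted p = 0.937 for each). The 36 antioxidant enzyme genes were higher (median log2 0.263, 28 positive, camera adjusted p = 0.00264), with 0 called members and 3 adjusted over the list alone. Of these, the methionine sulfoxide reductase gene msrb1a had a log2 fold change of 1.04 (SE 0.267, adjusted p = 0.133) and the mitochondrial carrier gene ucp1 one of 1.60 (SE 0.411, adjusted p = 0.133). The 40 neuron genes were higher (median 0.305, adjusted p = 0.00242; 0 called, 2 adjusted over the list alone), as were the 54 liver genes (median 0.462, adjusted p = 0.0128; hpdb called, 3 adjusted over the list alone). The 71 oxidative phosphorylation genes were also higher (median 0.162, adjusted p = 0.0285), with 0 members called on either count. The 42 lens genes, whose crystallin members can share reads, were higher too (median 1.56, 35 positive, adjusted p = 0.00264) with 0 called on either count. With the description number as a block, the lens shift had the opposite sign (adjusted p = 0.125 with the block shared by the groups and 0.312 within genotype). The shared block also ended the calls of oxidative phosphorylation (adjusted p = 0.109), epidermis (0.118) and unfolded protein and integrated stress response (0.118). The lower lists were sterol synthesis (26 genes, median -0.158, adjusted p = 0.0285; 0 called, 1 lower adjusted over the list alone) and epidermis (41 genes, median -0.269, adjusted p = 0.0325; 0 on either count). The 55 genes of unfolded protein and integrated stress response were lower as well (median -0.162, adjusted p = 0.0339; 0 on either count). In the sterol list the feedback regulator gene insig1 had a log2 fold change of -2.0 (SE 0.554, adjusted p = 0.161).

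The other 26 wild-type lists were not called, with camera adjusted p between 0.135 for inflammation and acute phase and 0.967 for heat shock response. With the description number as a shared block, camera called 5 of them: erythroid markers (adjusted p = 0.00104), Nrf2 and glutathione response (0.00736), conjugation enzymes and inflammation and acute phase (0.0258 each) higher, and ribosome proteins (0.0311) lower. None of these kept its call with an estimated correlation (adjusted p = 0.835 for ribosome proteins and 0.547 for the others). It called hypoxia response lower (adjusted p = 0.0378; adjusted p = 0.832 with an estimated correlation) with a term for the libraries numbered 4 or 5. The 26 p53 target genes had a median log2 fold change of 0.196 (adjusted p = 0.243), and their member with the smallest p was phlda3 at 0.67 (adjusted p = 0.328); 0 were called on either count. The 27 Nrf2 and glutathione response genes had a median of 0.239 (adjusted p = 0.342; 0 on either count), and the peroxiredoxin gene prdx1 a log2 fold change of 0.88 (SE 0.252, adjusted p = 0.174). The 37 erythroid marker genes had a median of 0.344 (adjusted p = 0.137; 0 on either count), with 2.18 (SE 0.668, adjusted p = 0.196) for the erythroid transcription factor gene klfd. Of the 16 Ahr target genes only cyp1a was called, and 2 were higher and 2 lower adjusted over the list alone (list median 0.228, adjusted p = 0.522). In the inflammation list irg1l, a gene of the macrophage and skin response to microbes, stood at -2.34 (SE 0.453, adjusted p = 0.0636). Median and test differed in sign for heat shock response, glycolysis, circadian clock, heart muscle, conjugation enzymes and ribosome proteins.

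The second comparison asked how tp53 mutant embryos respond, and the largest fold change was that of an Ahr target gene. In exposed mutants cyp1a rose 149-fold, from 0.821 ± 0.757 to 120 ± 79.8 CPM (log2 7.22, SE 0.686, adjusted p = 1.15e-05, n = 5 per group). The related P450 gene cyp1c1 (scaffold Zv9_NA892, 103570 to 106641, 1 exon) rose 19.8-fold, from 2.51 ± 0.892 to 50.3 ± 35.1 CPM (log2 4.31, SE 0.535, adjusted p = 3.65e-04). The Ahr repressor gene ahrra (chromosome 24, 43873326 to 43874578, 3 exons) rose 9.22-fold, from 1.18 ± 0.467 to 11.3 ± 8.02 CPM (SE 0.449 on the log2 scale, adjusted p = 0.00155). These were the 3 called members of the 16 Ahr targets, 5 adjusted over the list alone, and the list was higher (median log2 0.273, camera adjusted p = 3.95e-05; adjusted p = 0.0832 with an estimated correlation). Its score was 3.65 ± 0.455 in exposed and 2.5 ± 0.232 in unexposed mutants, with no overlap (two-sided exact permutation p = 0.00794, the smallest possible, 0.09 after adjustment over the lists). Exposed mutant library 5 had the lowest cyp1a of its group, 12.4 CPM against 92.9 to 234 in the other 4, and still lay above all unexposed libraries.

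**Figure D2:**
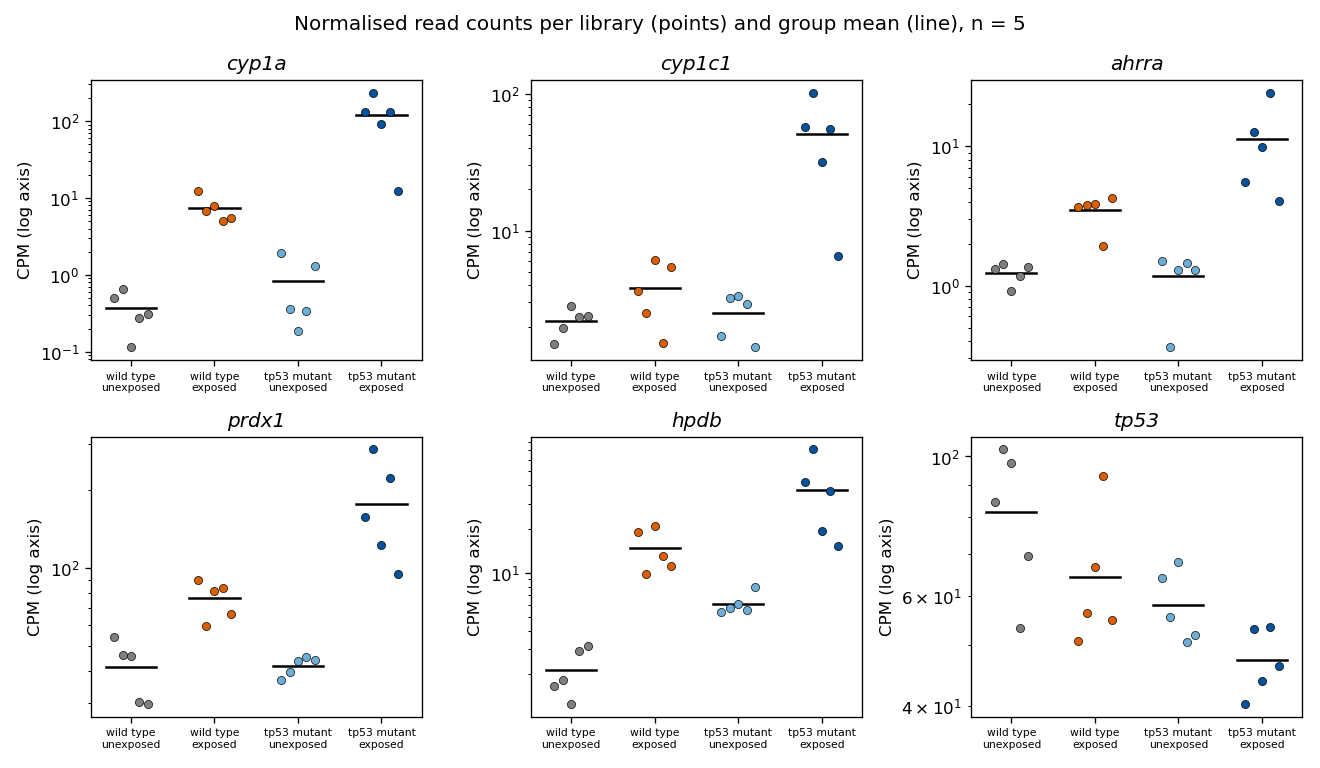
CPM on a log axis in each library for cyp1a, cyp1c1, ahrra, prdx1, hpdb and tp53, by group, with 5 points per group and a line at the group mean. Mean cyp1a was 0.37 in unexposed and 7.51 CPM in exposed wild type, and 0.821 in unexposed and 120 CPM in exposed mutants, while mean tp53 stayed between 47.4 and 81.5 CPM.

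Among genes of the Nrf2 and antioxidant lists, 4 of 27 and 4 of 36 rose in exposed mutants, with prdx1 and txn counted in both lists. The gene prdx1 (chromosome 2, 5749023 to 5758079, 6 exons) encodes a peroxiredoxin that breaks down peroxides, and rose 4.2-fold from 41.9 ± 3.49 to 176 ± 77.5 CPM (log2 2.07, SE 0.259, adjusted p = 3.65e-04). The thioredoxin gene txn rose 2.55-fold (log2 1.35, SE 0.274, adjusted p = 0.0239). The glutathione reductase gene gsr rose 2.33-fold (SE 0.288 on the log2 scale) and the conjugate export pump gene abcc2 9.07-fold (SE 0.75), both with adjusted p = 0.0414. These were the 4 called Nrf2 and glutathione response genes, and 9 were higher adjusted over the list alone. The list was higher (median log2 0.639, 24 positive, camera adjusted p = 1.13e-08; adjusted p = 0.316 with an estimated correlation), and its score was 5.49 ± 0.371 against 4.79 ± 0.321 (two-sided exact permutation p = 0.0159, 0.108 adjusted). Antioxidant enzymes were higher by camera, with 6 members called adjusted over the list alone (median 0.154, camera adjusted p = 4.29e-04; adjusted p = 0.425 with an estimated correlation). Among the called members were the methionine sulfoxide reductase gene msrb2 (chromosome 24, 17590928 to 17596933, 5 exons), up 7.86-fold (SE 0.447 on the log2 scale, adjusted p = 0.00294), and ucp1, up 5.84-fold (log2 2.55, SE 0.416, adjusted p = 0.00624). Conjugation enzymes were higher with 2 of 38 members called and 6 adjusted over the list alone (median 0.509, camera adjusted p = 2.76e-04; adjusted p = 0.425 with an estimated correlation). The sulfotransferase gene sult6b1 was 1 of them, up 4.03-fold (log2 2.01, SE 0.446, adjusted p = 0.0323). Heat shock response genes were higher with 2 of 32 called and 3 adjusted over the list alone: hsp70 rose 5.54-fold (adjusted p = 0.0321) and hsp90aa1.1 rose 3.59-fold (adjusted p = 0.0321). Their list median was 0.451 (camera adjusted p = 7.77e-05; adjusted p = 0.403 with an estimated correlation).

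Of 54 tested liver genes 21 rose in exposed mutants, 39 were called adjusted over the list alone and 50 had a positive fold change. The list was higher, with a median of 2.03 on the log2 scale (camera adjusted p = 5.67e-27; adjusted p = 0.0832 with an estimated correlation). The fibrinogen gene fga (chromosome 1, 9142184 to 9147606, 6 exons) rose 10.5-fold (log2 3.39, SE 0.694, adjusted p = 0.0251). The gluconeogenesis gene pck1 rose 11.8-fold (SE 0.721 on the log2 scale, adjusted p = 0.0239), and the retinol-binding protein gene rbp2b rose by a log2 fold change of 3.35 (SE 0.545, adjusted p = 0.00624). The plasminogen gene plg rose 5.23-fold (adjusted p = 0.00754), the antiplasmin gene serpinf2b 6.94-fold (adjusted p = 0.00993), and hpdb 5.94-fold (adjusted p = 0.00161). The liver score was 4.77 ± 0.858 in exposed and 3.1 ± 0.585 in unexposed mutants, and the intestine score 3.21 ± 0.478 and 1.96 ± 0.265, both without overlap (two-sided exact permutation p = 0.00794 each, 0.09 adjusted). Of 20 intestine genes 3 were called and 9 adjusted over the list alone, among them pck1 and the brush border peptidase gene dpp4, up 5.96-fold (log2 2.58, SE 0.523, adjusted p = 0.0239). The intestine list was higher (median 1.02, camera adjusted p = 4.76e-07) and was the only one of the 13 called lists that kept its call with an estimated correlation (adjusted p = 0.035). With both that and a term for the libraries numbered 4 or 5, intestine and liver were called (adjusted p = 0.0435 each), and with the description number as a shared block neither was (0.063 each). In inflammation and acute phase, 8 of 44 members were called, 14 higher and 1 lower adjusted over the list alone (median 0.0937, camera adjusted p = 0.0042; adjusted p = 0.425 with an estimated correlation). The complement gene cfb rose 7.81-fold (log2 2.96, adjusted p = 0.0257; log2 2.16, adjusted p = 0.0867 without exposed mutant library 1), and 5 of the 8 are also liver list members.

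**Figure D3:**
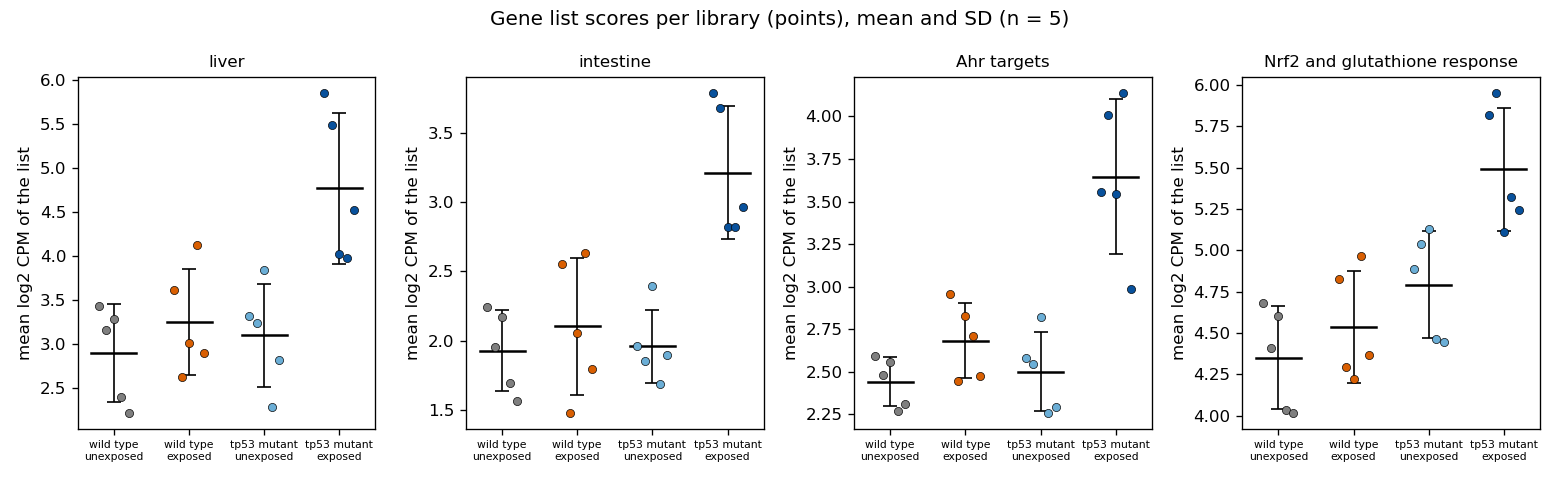
List scores (mean log2 CPM of the tested members) in each library for the liver, intestine, Ahr target and Nrf2 and glutathione response lists, by group, with 5 points per group and the mean ± SD. In exposed mutants the liver score was 4.77 ± 0.858 and the intestine score 3.21 ± 0.478, against 3.1 ± 0.585 and 1.96 ± 0.265 in unexposed mutants.

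Skeletal muscle genes were also higher in exposed than in unexposed mutants, with 3 of 65 members called and 5 adjusted over the list alone (median log2 0.715, 56 positive, camera adjusted p = 8.09e-09; adjusted p = 0.425 with an estimated correlation). The list score was 5.592 in exposed and 4.951 in unexposed mutants, against 5.674 in exposed and 5.572 in unexposed wild type. Exposed mutants thus stood near the wild-type level, and the rise started from a low score in unexposed mutants. The called members were the myogenic regulator gene myod1 (log2 1.78, SE 0.388, adjusted p = 0.0321) and calcium handling genes. These were the channel gene cacna1sb (log2 1.85, SE 0.45, adjusted p = 0.0471) and the release channel gene ryr1b (log2 1.71, SE 0.424, adjusted p = 0.0495). Neutrophil and macrophage genes were higher with 1 of 29 called, the collagenase gene mmp13a, up 10.8-fold (log2 3.43, SE 0.65, adjusted p = 0.0144), and 3 adjusted over the list alone. Its exposed libraries ranged from 2.84 to 32.5 CPM, and without exposed mutant library 1 its log2 fold change was 2.457 (adjusted p = 0.0636). Their median was 0.284 (camera adjusted p = 0.043; adjusted p = 0.6 with an estimated correlation). The 40 neuron genes had a median of 0.0312 (camera adjusted p = 0.0408; adjusted p = 0.911 with an estimated correlation; 0 called, 2 adjusted over the list alone). Sterol synthesis genes were lower (26 genes, median -0.385, camera adjusted p = 0.00817; adjusted p = 0.243 with an estimated correlation), with 0 called and 1 higher and 2 lower adjusted over the list alone. The lens list was called lower by camera (adjusted p = 0.0315; adjusted p = 0.911 with an estimated correlation) although its median was 0.148 and its mean 0.182, with 0 called on either count. With a term for the libraries numbered 4 or 5, camera gave adjusted p = 0.0671 for lens and 0.0524 for neurons. With the description number as a block, it gave 0.103 for neutrophils and macrophages (shared by the groups) and 0.183 for neurons (within genotype).

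In exposed mutants 4 genes were called lower. The thioredoxin-interacting protein gene txnipa (chromosome 19, 24974120 to 24977991, 6 exons) fell from 452 ± 152 to 182 ± 34.9 CPM (log2 -1.31, SE 0.264, adjusted p = 0.0236). The others were rbm8a, of the exon junction complex (log2 -0.90, SE 0.157, adjusted p = 0.00853), the nucleolin gene ncl (log2 -0.74, SE 0.168, adjusted p = 0.0371) and rab43 (log2 -0.63, SE 0.153, adjusted p = 0.0481). Other genes with large rises were lgals2b, a galectin gene (20.7-fold, adjusted p = 0.0106), the complement gene c3a (12.1-fold, log2 3.6, adjusted p = 0.0321), cyp2aa8 (10.9-fold, adjusted p = 0.0301) and trim62 (10.4-fold, adjusted p = 0.0371). For c3a the exposed libraries ranged from 37.9 to 600 CPM, and without exposed mutant library 1 its log2 fold change was 2.516 (adjusted p = 0.0992). The heart field transcription factor gene nkx2.5 rose 3.54-fold (adjusted p = 0.00853) as the only called heart muscle member. The mitochondrial glycine carrier gene slc25a38a rose 4.45-fold (adjusted p = 0.0262) as the only called gene of heme synthesis. The glutamine synthetase gene glula rose 2.82-fold (adjusted p = 0.0486) as the only called gene of glia and progenitors. Of the 26 p53 targets 0 were called, with 1 higher and 1 lower adjusted over the list alone (median 0.0724, camera adjusted p = 0.824). Their cell cycle inhibitor btg2 stood at -1.19 (SE 0.306, adjusted p = 0.0561) and ei24 at 1.56 (SE 0.463, adjusted p = 0.0976). Of the 37 erythroid markers 0 were called on either count (median -0.161, camera adjusted p = 0.654, direction up). The directional fry test called 5 lists in mutants: Ahr targets and intestine (adjusted p = 0.00115 each), liver (0.00472), sterol synthesis (0.0391) and Nrf2 and glutathione response (0.0394). Its smallest value was 0.507 in the wild-type exposure effect, 0.112 in the difference of the effects and 0.0669 between unexposed genotypes. For movement in either direction, fry called 9 lists in mutants: Ahr targets, inflammation and acute phase, intestine, antioxidant enzymes, liver, Nrf2 and glutathione response, sterol synthesis, conjugation enzymes, and neutrophils and macrophages (adjusted p from 2.81e-08 to 0.0432). It called Ahr targets in wild type (adjusted p = 0.0226) and no list in the difference of the effects (smallest 0.0735). Between unexposed genotypes it called Ahr targets (adjusted p = 0.00613), sterol synthesis and exocrine pancreas (0.0318 each) and inflammation and acute phase (0.0445). In all, 21 lists were not called, with camera adjusted p from 0.0554 for exocrine pancreas, where 1 of 10 members was called, to 0.976 for heme synthesis. Ribosome proteins were called higher (adjusted p = 0.0132; adjusted p = 0.93 with an estimated correlation) with a term for the libraries numbered 4 or 5.

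Among the remaining lists in exposed mutants, camera adjusted p was 0.79 for unfolded protein and integrated stress response, 0.312 for glycolysis, 0.79 for hypoxia response, 0.417 for DNA replication and cell cycle, 0.385 for apoptosis and 0.493 for circadian clock. It was 0.332 for ribosome proteins, 0.654 for oxidative phosphorylation, 0.583 for photoreceptors, 0.152 for heart muscle, 0.523 for endothelium and 0.304 for cartilage and bone. It was 0.79 for epidermis, 0.348 for ionocytes, 0.438 for pigment cells, 0.951 for hatching gland and 0.146 for glia and progenitors. Median and test differed in sign for erythroid markers, heme synthesis, circadian clock and unfolded protein and integrated stress response, and median and mean for DNA replication and cell cycle.

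In total edgeR called 139 genes in exposed mutants, 135 higher and 4 lower, 24 of them with placeholder symbols, and 1714 had an unadjusted p under 0.05. The count fell to 27, 28, 33, 34 and 67 without unexposed mutant library 2, 5, 4, 1 or 3 and to 29 and 33 without exposed mutant library 2 or 1. It was 331 without exposed mutant library 5 and 254 without exposed wild-type library 3. Of the 36 called genes singled out by the naming rule, 13 kept their call in all 20 fits that each left out a library: cyp1a, lgals2b, cyp1c1, rbp2b, rbm8a, prdx1, msrb2, ucp1, ahrra, nkx2.5, hpdb, plg and serpinf2b. Leaving out 1 library moved the fold by over 1.5 times for c3a, mmp13a and cfb, as given above, and for abcc2 (log2 2.584, adjusted p = 0.118), trim62 (2.754, adjusted p = 0.098), cyp2aa8 (4.131) and lgals2b (5.12). With the description number as a block within genotype, which takes the mutant libraries as paired, 218 genes were called, 89 of the 139 among them. There the calls of rbm8a, ncl, rab43, abcc2, slc25a38a, hsp70, myod1, cacna1sb and ryr1b ended, with adjusted p between 0.0502 for rbm8a and 0.162 for abcc2. With a term for the libraries numbered 4 or 5 the count was 562 (416 higher, 146 lower) and held all 139. It was 257 among those libraries alone and 376 among the others, with 60 and 90 of the 139. Tested against a fold change of 1.5, 25 genes were called, DESeq2 called 562 and limma-voom 51, and the 10 mutant libraries alone gave 10.

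The third comparison asked whether the response to exposure differed between genotypes, and no single gene passed the test. Wild type and mutants were exposed in separate experiments, so such a difference cannot be told apart from one between the experiments. Only an additive shift of a whole experiment cancels in it. The fold of cyp1c1 was larger in mutants than in wild type by 3.60 on the log2 scale (SE 0.729, adjusted p = 0.835, the smallest of all genes). The prothrombin gene f2 differed by 3.21 (SE 0.827), serpinf2b by 2.65 (SE 0.697), cyp2aa8 by 3.76 (SE 1.0), the kinase gene dapk2 by 2.85 (SE 0.669) and hsp90aa1.1 by 2.12 (SE 0.565), each with adjusted p = 1. The early response gene fos differed by -2.75 (SE 0.705), and the brain fatty acid binding gene fabp7b by -1.90 (SE 0.504), also with adjusted p = 1. Mean fos was 24.8 CPM in unexposed and 7.72 in exposed mutants, against 4.37 in unexposed and 9.56 in exposed wild type. For prdx1 the difference was 1.19 (SE 0.354), for msrb2 1.90 (SE 0.619), for tp53 0.05 (SE 0.28) and for gata1a -1.66 (SE 0.932), with adjusted p = 1 for each. With edgeR 0 genes were called and 399 had an unadjusted p under 0.05; limma-voom called 0 and DESeq2 called 1, cyp1c1 (adjusted p = 0.0109). Without exposed mutant library 5 edgeR called 1 gene, cyp1c1 (adjusted p = 0.00732), and among the libraries not numbered 4 or 5 it called 5, prox2, fabp7b, fos, si:dkey-15h8.11 and zgc:101540.

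By list, camera called 9 differences between the exposure effects, of which only intestine kept its call with an estimated correlation (adjusted p = 0.0491; the other 8 between 0.0824 and 0.716). That call too was lost with a term for the libraries numbered 4 or 5 (adjusted p = 0.0898) and with the description number as a shared block (0.163). The difference, mutant minus wild type, was positive for liver (median 1.56), intestine (1.18), Ahr targets (0.624) and Nrf2 and glutathione response (0.574). It was also positive for skeletal muscle (0.692), heat shock response (0.405), conjugation enzymes (0.373) and unfolded protein and integrated stress response (0.157), and negative for lens (-1.51). The mutant effect, this difference and the unexposed genotype comparison all use the unexposed mutant libraries. Their skeletal muscle score was 4.951, against 5.572 in unexposed wild type, so these results are not independent of each other. For unfolded protein and integrated stress response the score effect was 0.0596 in mutants and -0.131 in wild type, and for lens -0.512 and 0.821. Of their members 0 were called over all genes. Adjusted over the list alone, 4 Ahr target, 3 liver and 2 heat shock genes were called higher and 0 in the other 6. Their camera adjusted p ranged from 1.21e-18 for liver to 0.0183 for unfolded protein and integrated stress response. Exact permutation of the list scores gave its smallest two-sided p for intestine, 0.043 (0.614 adjusted), where the score effect was 1.25 in mutants and 0.178 in wild type. The other 25 lists were not called, with adjusted p from 0.0532 for glycolysis to 0.961 for endothelium. With the description number as a shared block, conjugation enzymes had adjusted p = 0.053 and unfolded protein and integrated stress response 0.0741. The same block called a positive difference for ribosome proteins (adjusted p = 3.47e-05) and glycolysis (0.0262), and a negative one for erythroid markers (0.00414), apoptosis (0.0431) and hatching gland (0.0448). With an estimated correlation these had adjusted p = 0.928, 0.606, 0.781, 0.781 and 0.53. A positive difference was called for epidermis (adjusted p = 0.00627), glycolysis (0.00731), ribosome proteins (0.0138) and inflammation and acute phase (0.0465) with a term for the libraries numbered 4 or 5. With an estimated correlation as well they had adjusted p = 0.955, 0.603, 0.955 and 0.666. For epidermis the score effect was -0.0298 in mutants and -0.423 in wild type.

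The exposure effects of both genotypes shared 2 called genes, cyp1a and hpdb, against 0.0476 expected among 11334 tested genes (one-sided Fisher exact p = 8.32e-04). Of the 135 genes that rose in exposed mutants, 126 (93.3%) had a positive fold change in wild type, with a median log2 of 0.819 there and 2.2 in mutants. For prdx1 the wild-type values went from 41.3 ± 10.7 to 76.2 ± 12.6 CPM, and for txnipa from 381 ± 99.6 to 162 ± 43.4 CPM, neither called. Across all 11334 genes, which are not independent replicates, the exposure effects had a Pearson r of 0.53 and a Spearman rho of 0.486. The overlap was 0 without unexposed wild-type library 2, 1 without unexposed wild-type library 3, 4 or 5 and 8 without exposed wild-type library 2. With a term for the libraries numbered 4 or 5 it was 22 higher genes against 2.39 expected (one-sided Fisher exact p = 4.35e-16). The lower genes shared were 12 against 0.438 (one-sided Fisher exact p = 5.68e-15), among them txnipa, ncl and the sterol regulator gene srebf2. The Fisher tests of the overlap treat genes as independent, so their p-values do not measure the spread between libraries.

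The fourth comparison asked how unexposed mutants differed from unexposed wild type, a difference that is also that between the experiments. The clearest change was in kcnk5a (chromosome 17, 48839352 to 48861566, 5 exons), a potassium channel gene. It stood at 2.23 ± 0.811 CPM in mutants and 42.4 ± 17.1 in wild type (19.3-fold lower, log2 -4.27, SE 0.419, adjusted p = 2.03e-05, n = 5 per group). Exposed embryos had 1.96 ± 0.553 CPM in mutants and 49.3 ± 25.7 in wild type. The gene ggact.2 (chromosome 1, 2206949 to 2209919, 2 exons) had 0 reads in unexposed mutants and 276 in wild type, at least 72.2-fold lower (floor of 3 counts over the group, adjusted p = 0.0111). The gene rfesd had 0 reads against 52, at least 13.6-fold lower (adjusted p = 0.0314). Exposed mutants had 1.60 ± 2.26 CPM of ggact.2 and exposed wild type 8.74 ± 3.86. The lipid droplet gene plin2 had 1 read against 85, a ratio of 66.7 (95% counting interval 11.7 to 2670, adjusted p = 0.0107). The adenylate kinase gene ak7a was also lower, at 4.95 ± 1.78 against 24.8 ± 11 CPM (log2 -2.33, SE 0.338, adjusted p = 0.00258). Further lower genes were prox2 (log2 -3.71, adjusted p = 0.0176), illr4 (log2 -4.13, adjusted p = 0.0201) and rxfp2b (log2 -2.55, adjusted p = 0.0295). In the other direction, ccdc125 (chromosome 5, 27816113 to 27826412, 11 exons), on the chromosome of tp53, was higher in mutants, at 26.4 ± 15.5 against 3.86 ± 1.22 CPM (6.84-fold, log2 2.77, SE 0.466, adjusted p = 0.00702). The Ahr target list member foxq1a was higher too, at 30.7 ± 21.5 against 3.77 ± 0.901 CPM (8.08-fold, log2 3.01, SE 0.544, adjusted p = 0.0107). The selenoprotein gene selm rose 4.13-fold (adjusted p = 0.00534), cuedc1b 3.85-fold (adjusted p = 0.00417) and ttll2 10.6-fold (adjusted p = 0.019).

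Inflammation and acute phase was higher in unexposed mutants (44 genes, median 0.436, camera adjusted p = 9.6e-05; adjusted p = 0.51 with an estimated correlation), with 3 called members and 4 higher and 1 lower adjusted over the list alone. They were the transcription factor genes fos (log2 2.48, SE 0.507, adjusted p = 0.022) and cebpd (log2 1.72, SE 0.355, adjusted p = 0.0232) and the prostaglandin synthesis gene ptgs2b (log2 1.93, SE 0.459, adjusted p = 0.0483). Apoptosis genes were higher (35 genes, median 0.36, adjusted p = 6.06e-04; adjusted p = 0.51 with an estimated correlation), and the proapoptotic gene bik was the called member (log2 1.85, SE 0.429, adjusted p = 0.0407), 1 adjusted over the list alone. Neutrophil and macrophage genes were higher (29 genes, median 0.502, adjusted p = 5.82e-05; adjusted p = 0.51 with an estimated correlation), with the cathepsin gene ctsk called (log2 1.19, SE 0.266, adjusted p = 0.0328; 1 adjusted over the list alone). Epidermis genes were higher (41 genes, median 0.689, adjusted p = 5.77e-06; adjusted p = 0.673 with an estimated correlation), with the skin regulator gene tp63 called (log2 1.25, SE 0.291, adjusted p = 0.042; 3 adjusted over the list alone). The krt4 share of counts, which was not tested, ranged from 6.28% to 13.6% in these libraries and from 3.38% to 10.1% in unexposed wild type. Skeletal muscle genes were lower (65 genes, median -0.749, adjusted p = 2.86e-09; adjusted p = 0.52 with an estimated correlation), with the calcium store gene casq1a called (log2 -1.45, SE 0.305, adjusted p = 0.0266; 11 lower adjusted over the list alone). Conjugation enzymes were higher (38 genes, median 0.347, adjusted p = 0.00121; adjusted p = 0.564 with an estimated correlation), with the glutathione transferase gene gstt1b called (log2 1.29, SE 0.296, adjusted p = 0.0374; 2 adjusted over the list alone). Oxidative phosphorylation was higher (71 genes, median 0.126, adjusted p = 0.025; adjusted p = 0.842 with an estimated correlation), while its called member, the muscle form cox7a1, was lower (log2 -2.70, SE 0.547, adjusted p = 0.0201; 1 lower adjusted over the list alone).

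Other lists were called without a called member, and none of the 17 called lists kept its call with an estimated correlation (adjusted p between 0.406 and 0.842). Higher were Nrf2 and glutathione response (27 genes, median 0.399, adjusted p = 1.45e-04), antioxidant enzymes (36 genes, median 0.244, adjusted p = 7.26e-04) and sterol synthesis (26 genes, median 0.375, adjusted p = 0.00131). With an estimated correlation these had adjusted p = 0.52, 0.52 and 0.406. Also higher were erythroid markers (37 genes, 31 positive, median 0.579, adjusted p = 0.00417), hatching gland (10 genes, median 1.01, adjusted p = 0.00677) and heme synthesis (16 genes, median 0.302, adjusted p = 0.0176), with adjusted p = 0.689, 0.52 and 0.613 with an estimated correlation. Neurons (40 genes, median -0.497, adjusted p = 0.00319) and DNA replication and cell cycle (82 genes, median -0.292, adjusted p = 0.00415) were lower, with adjusted p = 0.689 and 0.842 with an estimated correlation. So were lens (42 genes, median -0.619, adjusted p = 0.0214) and photoreceptors (39 genes, median -0.79, adjusted p = 0.0375; 0.0525 with the description number as a shared block), both with adjusted p = 0.842 with an estimated correlation. Adjusted over the list alone, 3 antioxidant, 2 sterol, 2 hatching gland and 1 heme synthesis gene were higher. On the same count 2 erythroid markers were higher and 1 lower, 1 cell cycle gene was lower, and 0 were called for Nrf2, neurons, lens and photoreceptors. The 17 lists not called ran from adjusted p = 0.0602 for glycolysis to 0.978 for intestine. Ribosome proteins and ionocytes among them were called higher with a term for the libraries numbered 4 or 5 (adjusted p = 0.0107 and 0.039) and with the description number as a shared block (0.0181 and 0.026). With an estimated correlation as well, the adjusted p = 0.822 and 0.432 with the term and 0.824 and 0.304 with the block. Of those, the 26 p53 targets had a median of 0.00406 (adjusted p = 0.761; 0 called, 1 higher adjusted over the list alone). The lists not called also held called members: the phosphofructokinase gene pfkma (log2 -1.45, SE 0.329, adjusted p = 0.0359) in glycolysis and the chaperone activator gene ahsa1 (log2 -2.11, SE 0.408, adjusted p = 0.0161) in heat shock response. Others were the tyrosine breakdown gene fah (log2 1.36, SE 0.243, adjusted p = 0.0104) in liver and the proton exchanger gene slc9a1 (log2 -1.53, SE 0.348, adjusted p = 0.0367) in ionocytes. Glycolysis also held the aldolase gene aldoca, with 3 reads in mutants against 63, a ratio of 16.5 (95% counting interval 5.39 to 82.1, adjusted p = 0.0374).

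In total edgeR called 105 genes between unexposed genotypes, 48 higher and 57 lower in mutants, 35 of them with placeholder symbols, and 1574 had an unadjusted p under 0.05. The count was 30, 32 and 35 without unexposed mutant library 2, 3 or 1, and 36, 37, 57 and 69 without unexposed wild-type library 3, 2, 1 or 4. Of the 29 called genes singled out by the naming rule, foxq1a, ccdc125, selm, cuedc1b, arhgdig, ggact.2, plin2, kcnk5a, ak7a and fah kept their call in all 20 fits that each left out a library. Leaving out 1 unexposed mutant library moved the log2 fold change to -6.76 for plin2, -4.959 for illr4 and -4.586 for aldoca. With the description number as a block, which takes these libraries as paired, 839 genes were called (508 higher, 331 lower), with all 105 among them. With a term for the libraries numbered 4 or 5 the count was 680 (401 higher, 279 lower), also with all 105. It was 25 among those libraries alone and 1018 among the others, with 13 and 98 of the 105. Tested against a fold change of 1.5, 19 genes were called, DESeq2 called 374, and the 10 unexposed libraries alone gave 166. Of 100 splits of these 10 libraries, 6 gave at least 105 genes, the real one included.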

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

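The 7 distant libraries and the 9 list differences below came from rules fixed before the data were examined, while all tests of what lies behind the liver pattern were chosen after the result was seen.

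Both libraries numbered 6 in the descriptions were deep, exposed mutant library 5 with 13304175 counts and exposed wild-type library 4 with 12853855. The other 4 exposed mutant libraries had 2974594 to 5492492. For exposed mutant library 5 the gap to its nearest neighbour was 0.756 of the group's range, above the critical value of 0.71 for 5 libraries. The same measure was 0.757 for gata1a in exposed mutant library 2 (log2 CPM -0.78 against 0.81 to 1.31 in the others) and 0.752 for celf4 in unexposed wild-type library 2 (4.62 against 5.34 to 5.57). It was 0.795 for mmp13a in unexposed mutant library 2 (-0.28 against 0.39 to 0.56) and 0.905 for rab43 in exposed wild-type library 3 (5.00 against 5.38 to 5.42). It was 0.906 for ak7a in unexposed mutant library 1 (3.07 against 2.12 to 2.21). For plin2 in unexposed mutant library 5 it was 1, which came from 1 read against 0 in the other libraries of the group. The distant values of gata1a (0.3 CPM) and mmp13a (0.539 CPM) also rest on few reads. Chance alone sets apart about 1 group in 20, and 7 of 172 groups tested were set apart here.

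By the preset-correlation camera test the response to exposure differed between genotypes for 9 lists. Each genotype was exposed in its own experiment, so these differences may equally lie between the experiments. Only intestine kept its call with an estimated correlation, and none did with both that and a term for the libraries numbered 4 or 5 (adjusted p = 0.0898 for intestine). The 9 lists had the following adjusted p and mutant and wild-type effects on the list score (log2, n = 5 per group). For liver the adjusted p = 1.21e-18, with effects of 1.67 and 0.355. For lens it was 1.74e-08, with -0.512 and 0.821, and for skeletal muscle 1.57e-07, with 0.641 and 0.102. For Nrf2 and glutathione response it was 8.16e-07, with 0.697 and 0.185, and for intestine 1.26e-06, with 1.25 and 0.178. For Ahr targets it was 2.49e-05, with 1.15 and 0.239, and for heat shock response 3.18e-05, with 0.553 and 0.00991. For conjugation enzymes it was 0.00153, with 0.498 and 0.0378, and for unfolded protein and integrated stress response 0.0183, with 0.0596 and -0.131. With an estimated correlation the adjusted p = 0.244 for liver, 0.716 for lens, skeletal muscle and conjugation enzymes, 0.442 for Nrf2, heat shock and unfolded protein response, 0.0824 for Ahr targets and 0.0491 for intestine. Two-sided exact permutation of the exposure assignments gave p = 0.043 for intestine and 0.0448 for Ahr targets, both 0.614 after adjustment over the lists, and p between 0.0542 and 0.27 for the other 7.

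The liver genes had the smallest adjusted p of these differences, and their higher levels in exposed mutants (median log2 2.03) were weighed against technical explanations. An additive shift of the libraries numbered 4 or 5 cancels here by design, since each group holds 2 of them, and so was not tested. The score difference was 1.45 (SE 0.268) within the 4 mutant libraries so numbered and 1.82 (SE 0.442) within the other 6. Both lay above a bound of 0.837, so neither side alone carried it. A single library is not enough to account for the higher levels, since the full difference of 1.67 was at least 1.4 without any 1 of the 10 mutant libraries. A larger amount of liver tissue in exposed mutants is a candidate explanation that stays open. The 10 most abundant liver genes had a median log2 fold change of 2.61, which does not decide, since they belong to the list in question; 7 lay above the 1.01 it would need, while aldob (0.225), rbp4 (0.353) and cyp2y3 (0.591) lay below. Of the 54 tested liver genes, 6 belong to the inflammation and acute phase list too, 1 to intestine and 1 to glycolysis, and unexposed embryos expressed them as well. A response of the mutants to exposure, through more output per liver cell or a shift in stage, may also play a part and stays open, as it was not tested.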

How the results depend on the processing

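The fits with a term for the libraries numbered 4 or 5, with these or the other libraries alone, and with blocks on the description number, were chosen after the results were seen, as was the title-number block shared by the groups for the genotype difference. Counts follow the order wild-type exposure, mutant exposure, difference of the effects, genotype, overlap, where the fits here gave 4, 139, 0, 105 and 2. Other scaling factors and other filters on low counts stayed within 1.5 times of these, and scaling left the median log2 fold change of all genes between -0.0425 and 0.0573. DESeq2 gave 172, 562, 1, 374 and 57. For limma-voom the counts that moved were 0 for wild type, 51 for mutants and 0 for the overlap, and with 1 surrogate variable they were 226, 663, 447 and 65, with the difference at 0. With the batch term they were 99, 562, 680 and 34, with libraries numbered 4 or 5 alone 0, 257, 25 and 0, and with the others alone 578, 376, 5, 1018 and 56. Against a fold change of 1.5 they were 2, 25 and 19, and the 10 libraries of a genotype alone gave 2 and 10, the 10 unexposed libraries 166. Leaving out 1 library gave 0 to 20, 27 to 331, 0 to 1, 30 to 135 and 0 to 8. The surrogate variable had r = 0.856 with being numbered 4 or 5; for the other changes the cause was not tested, beyond the fewer libraries in some fits.

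As a pairing check, the replicate numbers in the titles gave r between -0.331 and 0.317 over the 5 mutant pairs and between -0.606 and 0.133 over the 5 wild-type pairs, so they do not pair the libraries. As a block within genotype they gave 0 genes for wild type, 9 for mutants and 0 for the overlap, and as a block shared by the groups 38 for mutants and 66 for genotype. The description number as a shared block gave 56, 546, 839 and 35, and within genotype 0, 218 and an overlap of 0, with the difference at 0 in both. Under it the lens list in wild type was reversed (adjusted p = 0.125 shared, 0.312 within genotype); the cause was not tested.

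Over all alternatives, 2474 cases of named genes were unchanged: called genes kept direction and call, and uncalled genes stayed uncalled. The call was lost in 573 cases and gained in 6, and called genes reversed in 0. Direction was not checked for the uncalled genes. The called lists kept their call in 1308 cases, lost it in 245 and reversed in 2. Lists not called, some of which gained a call, were not tallied. The 4 called wild-type genes kept their call in 107 of 144 cases, the 36 mutant ones in 964 of 1295 and the 29 genotype ones in 777 of 982. All these tallies include fits that left out a library of a group outside the comparison, and so can overstate how stable the calls are. In wild type, all 4 genes kept their call in every fit without a mutant library. Small changes can be missed: 14% to 19% of simulated 2-fold changes were recovered, and 36% to 46% with the batch term.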

Other observations

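The tests of depth, of a few abundant genes and of other splits of the samples were set before their results were seen, and the tests of gene length, of linked sequence and of the experiments after.

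The libraries whose descriptions carry the number 4 or 5 (2 in each group) differed from the other 3 in tissue gene content, in the same direction in all 4 groups for most lists. The score of epidermis genes differed by -1.61 ± 0.288 (log2, mean and SD over the 4 groups) and that of ribosome protein genes by -1.51 ± 0.453. The difference was -0.991 ± 0.412 for erythroid markers, -0.979 ± 0.234 for liver and -0.788 ± 0.235 for heme synthesis. Single genes differed by more, with -3.08 ± 0.961 for the embryonic globin hbbe3, -2.07 ± 1.03 for alas2, the first enzyme of erythroid heme synthesis, -1.85 ± 0.327 for krt4 and -2.16 ± 0.191 for the apolipoprotein apoa2. Neuron genes were higher by 0.856 ± 0.489 in all 4 groups, among them elavl4 at 1.24 ± 0.162, the GABA synthesis gene gad1b at 1.55 ± 0.263 and the synaptic gene snap25a at 1.08 ± 0.222. Of the 40 neuron genes 35 were higher and 5 lower on average, and the neuron marker elavl3 stood at -0.705 ± 1.04, from -1.98 to 0.538 by group. Endothelium was higher by 0.217 ± 0.136 in all 4 groups, and Ahr targets differed by -0.0947 ± 0.306, lower in 3 of 4. These 8 libraries were singled out after the principal components were seen, and no test is given for them.

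The separation of these 8 libraries was weighed against technical explanations. Depth is not enough to account for it, since with every library thinned to 1176919 counts the number explained 0.681 of the variance of the first component, against 0.67 before. A few abundant genes are not either, since without the 20 most abundant genes it explained 0.666. Gene length alone is not enough for the short ribosome protein genes, which shifted by -1.24 (SD 0.083 over 1000 matched lists) beyond genes of matched length. The matched genes themselves shifted by -0.304. This list was chosen after the data were seen and was among the most shifted, so it cannot measure a length bias over all genes. Different handling of these 8 libraries, such as another preparation or collection, could lie behind the separation and stays open. No biological explanation was tested because the design names none.

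The difference between unexposed genotypes was weighed in the same way. Sequence linked to the tp53 locus as the whole cause is argued against by positions, since 4.76% of the called genes (5 of 105) lay within 10 Mb of tp53 on its chromosome. Whether it plays a part for those 5, ccdc125, coro1ca, LOC561321, trmt2a and zgc:110340, stays open: 2.26 were expected within 10 Mb (Fisher exact p = 0.0761) and 1.33 within 5 Mb, where all 5 lie (Fisher exact p = 0.0108). With the term for the libraries numbered 4 or 5, 10 of 680 called genes lay within 5 Mb against 8.64 expected (Fisher exact p = 0.595), and 14 within 10 Mb against 14.6 (Fisher exact p = 1). The genotypes and the 2 experiments cannot be told apart, because 0 libraries of a genotype were in the other experiment. The effect of the tp53 allele itself therefore stays open.

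Other splits of the same libraries were counted for each comparison. For wild-type exposure 6 of 100 splits gave as many genes as the real 4, so chance cannot be excluded. The highest other, 2338, had all 4 libraries numbered 4 or 5 on one side. The 4 splits with that division called 0 to 2338 genes. The next highest, 677 and 112, had 1 of these libraries on one side, and splits with 2 on each side called at most 4. The larger counts thus came from uneven divisions, but an uneven division did not always give one. With the term for the libraries numbered 4 or 5, only the real split of 60 reached 99 (highest other 17). As 1 of 60 is the smallest share possible, this makes chance unlikely but does not exclude it. For mutant exposure 1 of 100 reached 139 (highest other 2), and 1 of 60 reached 562 with the term (highest other 326). Both were the real split, which makes chance unlikely without excluding it, and another split with the term called 187. Among the other splits that part as many pairs of description numbers the highest was 1 (12 splits), and 8 with the term (15 splits). For the difference of the effects the real count was 0, which all 100 regroupings reach whatever they call (highest 1225), so this count says nothing about chance. Between unexposed genotypes 6 of 100 reached 105 (highest other 2970). The 5 others that did so each had the 4 libraries numbered 4 or 5 on one side and called 441 to 2970 genes, while the rest called 0. So chance cannot be excluded there without regard to the numbers. With the term 1 of 60 reached 680 (highest other 0), which makes chance unlikely without excluding it. The other splits parting as many pairs called 0, 15 with the term and 11 without.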
